A study of Homo sapiens with 12 samples.

How the data were processed

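The series held 12 libraries from DLD1, an established human colorectal cancer cell line, taken at passage 5. Cells carried a non-targeting short hairpin RNA (shNC) or one against NAT10 (shNAT10), the enzyme that acetylates cytidine in RNA to N4-acetylcytidine (ac4C). Per the labels, 100 µg of total RNA was broken into pieces of 100 to 200 nt and immunoprecipitated with an antibody against ac4C, a method called acRIP-seq. Each of the 4 groups (input and immunoprecipitate of each hairpin) held 3 replicates, read as 150 bp pairs. Whether the replicates were separate cultures was not given in the sources used here, so spread is that between samples. A limma p for a gene also draws on the spread of other genes of like level.

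The authors deposited a gene table in FPKM, fragments scaled by gene length and library size, with columns for the 6 input libraries. Columns named NC with a number matched the shNC inputs by title. Columns named sh with a number were taken as the shNAT10 inputs by elimination, and 0 per-sample columns stayed unmapped. The immunoprecipitated libraries had no column there, so antibody enrichment per library was not analysed here. The authors also deposited a table of differential peaks. Per the file headers it gave each peak a fold enrichment, a p-value of the peak call, and the log2 fold change of a differential test with its FDR. Which hairpin stood in the numerator of that log2 fold change was not stated. Neither was the pooling of replicates, nor how a peak's fold was scaled. The processing notes of the authors named cutadapt 2.5, HISAT2 2.1.0 and HOMER 4.10.4 with no role for each, and both a human build (GRCh38) and a mouse build (GRCm38). Coordinates were read as GRCh38 and half-open, because 98.4% of the 2190 peaks whose gene symbol had a RefSeq gene lay within that gene in GRCh38, and 1167 of 1167 single-block peaks had a size equal to end minus start. Positions are printed counting from 1 with both ends included. The counting tool, annotation release and peak caller were not given in the sources used here.

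Whole fragments behind the deposited FPKM values were recovered with a scale for each library and a length for each gene. The scales came from RefSeq lengths of small RNAs and of the mitochondrial mRNAs. All 15014 genes above 0 came out whole within 0.001 fragments, a weak check, because each length was sought to make values whole. The recovered lengths of 13 of 13 mitochondrial mRNAs equalled their RefSeq lengths. Those lengths had helped to set the scales, so this was no independent check. On 3000 simulated genes with the true scales given, the method returned 97.4% exactly. Fragments on genes numbered 2758165, 2636810 and 2705387 in shNC replicates 1 to 3, and 1303818, 1233204 and 1224104 in the libraries labelled shNAT10. The authors' FPKM denominator was 0.979 to 1.27 times this sum, so it was not the plain sum. It was 3383204, 3284599 and 3426872 in shNC and 1389633, 1498313 and 1197889 in the libraries labelled shNAT10. The lowest ratio was in shNAT10 replicate 3 and the highest in shNC replicate 3. Small FPKM differences between the groups can thus depart from differences in fragment share. PCR copies were not marked, so a fragment is not an independent molecule. Fragments served for depth, the shares of values at 0, thinning and voom, and the recovered lengths for matching on gene length. Levels and all other tests came from the deposited FPKM values.

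Choices of groups, tests, gene lists, the rule for named genes and most alternatives were made before the data were examined. Input libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the libraries of the fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The fit draws each SE toward that of genes of like level, here with 212.6 prior degrees of freedom. SE and p therefore rest mostly on the spread of such genes and little on a gene's own replicates. Differences are shNAT10 minus shNC. NAT10 was also compared by an exact two-sided permutation test, which cannot give less than p = 0.1 for 3 against 3. There were 28 gene lists, and those with at least 5 tested members were compared with other genes by limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Replicate numbers did not pair the libraries: deviations from group means correlated across genes at 0.00, -0.02 and 0.01 between libraries of the same number, so the replicate block was an alternative only.

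Named genes were NAT10 and up to 10 genes per direction with the largest differences, among those past the test whose groups did not overlap. Genes annotated as pseudogenes were left out by biotype, which gave RNU1-28P as a small nuclear RNA. For each list, up to 2 members past the test were named, or else the most abundant member. From the deposited table came the 10 peaks of largest fold, peaks in NAT10, AIFM2 and KIF23, and up to 4 genes per enriched list. Genes with a peak were compared with other genes in the input data by camera, and by their median difference against 10000 random lists matched on mean level in 20 bins. Lists were tested among genes with a peak by Fisher's exact test, two-sided, with genes of mean FPKM of at least 1 in the shNC inputs as background. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

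The limma fit was tested on simulated, normally distributed values with changes in genes drawn at random. Their spread followed the mean level in these libraries, but the many values at 0 were not simulated. Each simulated gene had the spread typical of its level, as the fit assumes. Genes of wider spread were thus left out, and calls among unchanged genes may be too few for the real data. The fit called 0 of 40 genes at a log2 change of 1, 0 of 40 at 2 and 10 of 40 at 4. It called 27 of 40 at 6 and 39 of 40 at 8, and 8 of 10317 unchanged genes. The list test found a planted list in 50 of 50 simulated peak sets, with 2 false calls in 1200. Alternatives covered the pseudocount, filter, scaling, spread model, replicate block, thresholds, each replicate left out, peak thresholds, merged peaks and other backgrounds. A fit of all 12 libraries and a search of peak sequences for repeats were not run, since they needed immunoprecipitate columns or a genome sequence not used here.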

Results

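The data comprised gene levels (FPKM) in 6 input libraries of DLD1 colorectal cancer cells, 3 with the control hairpin shNC and 3 labelled shNAT10, and the authors' table of differential ac4C peaks. DLD1 is an epithelial line, and NAT10 is the acetyltransferase that writes ac4C on RNA. Fragments on genes ranged from 2636810 to 2758165 in shNC and from 1224104 to 1303818 in the libraries labelled shNAT10, a ratio of means of 2.15. Of 58302 genes listed, 15014 were above 0 in at least 1 library and 2399 in all 6. Genes above 0 numbered 8490 ± 175 (SD, n = 3) in shNC and 6967 ± 997 (SD, n = 3) in the libraries labelled shNAT10, where replicates 1 and 2 had 6348 and 6435 and replicate 3 had 8117. Mitochondrial mRNAs took 3.98% ± 0.435 (SD, n = 3) of fragments in shNC and 2.73% ± 0.610 (SD, n = 3) in the libraries labelled shNAT10.

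Values of single genes varied widely between replicates. HPRT1, a housekeeping enzyme of purine salvage, was listed at FPKM 0, 0.375 and 0.359 in shNC and at 157, 227 and 0 in the libraries labelled shNAT10. TBP, the TATA-binding protein, was listed at 0, 0 and 6.55, and at 0 in all 3 libraries labelled shNAT10. ACTB, which encodes beta-actin, was steadier, at 931, 1005 and 841 against 1080, 1000 and 1135. These 3 genes were chosen after their values were seen. Of the 7396 genes with at least 100 fragments in one shNC library, 3342 (45.2%) were at 0 in another shNC replicate, and the share was 48.7% (2340 of 4805) in the libraries labelled shNAT10. Correlation of log2 values across genes was 0.38 to 0.41 between replicates and 0.37 to 0.40 between groups, and genes are not independent replicates.

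**Figure D1:**
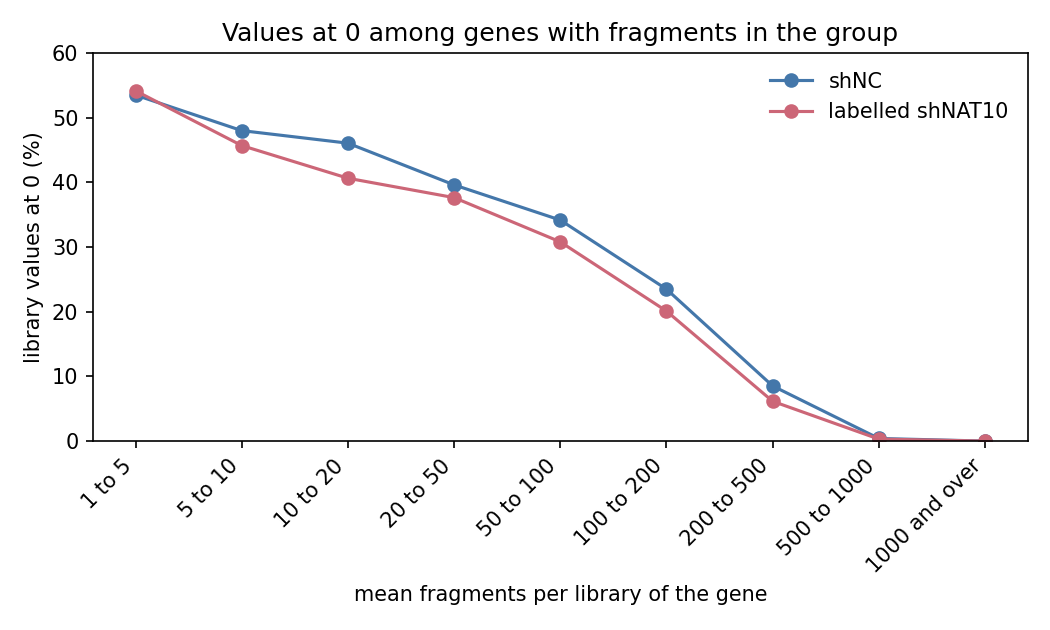
Share of library values listed at 0 (y axis, %) against the mean number of fragments per library of the gene (x axis, classes), for genes with fragments in the group; 3 input libraries per group. Among genes with a mean of 50 to 100 fragments, 34.2% of values in shNC and 30.8% in the libraries labelled shNAT10 were 0.

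The first comparison asked whether the targeted gene was lower. NAT10 (ENSG00000135372) was at FPKM 1.24, 3.95 and 2.89 in shNC replicates 1 to 3, from 22, 68 and 52 fragments. In the libraries labelled shNAT10 it was listed at 0 in replicate 1 and at 28.1 and 31.4 in replicates 2 and 3, from 0, 221 and 197 fragments. So 1 library of 3 was below every shNC library and 2 of 3 were above all of them, against what the label says. The difference in mean log2(FPKM + 1) was 1.48 (SE 1.86, 95% interval -2.18 to 5.15) and did not pass (limma adjusted p = 0.754; exact permutation p = 0.4, two-sided, smallest possible 0.1). With shNAT10 replicates 2 and 3 left out the difference was -1.81, and with a pseudocount of 0.01 it was -0.23. Without shNAT10 replicate 1, 2 or 3 it was 3.13, 0.70 and 0.62, and with voom 0.44. Every direction given here for the input libraries is that of the label.

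The second comparison asked which RNAs differed between the hairpins in input level, scaled to library size. Both ribosomal RNA copies past the test were higher in the libraries labelled shNAT10. RNA5-8SN4 (ENSG00000275215), a copy of the small RNA that pairs with the large-subunit ribosomal RNA, had FPKM 12349, 12033 and 11194 in shNC and 25257, 27478 and 33572 in the libraries labelled shNAT10, a log2 difference of 1.27 (SE 0.13, n = 3 per group, limma adjusted p = 7.28e-15). These levels came from 6392, 6047 and 5869 fragments in shNC and 5370, 6299 and 6153 in the libraries labelled shNAT10. The latter libraries held fewer fragments on genes, so RNA5-8SN4 rose in share and not in fragment number. Under quantile normalization its difference was 0.58 (limma adjusted p = 0.028). RNA5-8S4, another copy, rose by 2.31 (SE 0.43). RN7SL2, an RNA of the signal recognition particle that directs secretory proteins to the endoplasmic reticulum, rose by 1.14 (SE 0.15, limma adjusted p = 3.66e-09). Its groups overlapped, with FPKM 13166, 42174 and 12464 in shNC and 30020, 28116 and 88099 in the libraries labelled shNAT10. That SE came mostly from genes of like level and does not measure the spread between these replicates. The RN7SL2 call held in 2 of 6 fits with a replicate left out. The difference was 0.61 without shNAT10 replicate 3 (limma adjusted p = 0.356), and 0.88, 1.72 and 0.84 without shNC replicates 1, 2 and 3 (0.779, 0.639 and 0.775), fits in which RNA5-8SN4 alone passed. With robust eBayes RN7SL2 did not pass (0.743). RNU1-28P, a spliceosomal small nuclear RNA copy, rose by 2.71 (SE 0.59), and MIR1282 rose by 0.59 (SE 0.13), a call kept in 6 of 22 alternatives and 1 of 6 fits with a replicate left out. Its difference was 0.32 on the TPM scale, 0.44 with median ratio scaling, 0.38 by voom on recovered fragments and -0.12 under quantile normalization, none past the test.

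Many other genes past the test were antisense RNAs that were near 0 in one group. AC090617.4 had 16.1, 0.721 and 0 in shNC and 212, 615 and 1232 in the libraries labelled shNAT10, a log2 difference of 7.46 (SE 1.39). AC007193.3 rose by 6.55 (SE 1.42) and AC005841.1 by 5.51 (SE 1.34), the latter with 225 FPKM in shNC replicate 1. The AC007193.3 call held in 10 of 22 alternatives and 1 of 6 fits with a replicate left out. For AC005841.1 it held in 7 of 22 and 0 of 6. In the other direction, the lincRNA AC108693.2 had 335, 228 and 409 in shNC and was listed at 0 in all 3 libraries labelled shNAT10. The antisense RNAs AC025576.2 (155, 103 and 294 in shNC), AL354794.1 (73.9, 344 and 150) and AC124283.1 (98.4, 207 and 104) were also listed at 0 in all 3. AC027309.1 fell by 6.69 (SE 1.56) and AL512288.1 fell by 6.02 (SE 1.51), each above 0 in 1 library labelled shNAT10.

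In all, limma tested 10517 genes and called 20, of which 9 were higher and 11 lower, and 389 had an unadjusted p under 0.05. By annotation, the 20 comprised 9 antisense RNAs, 2 ribosomal RNAs, 2 small nuclear RNAs and 2 miscellaneous RNAs. The others were 2 pseudogenes, 1 lincRNA, 1 microRNA locus and 1 unclassified transcript. By limma, 0 of 8140 protein-coding genes passed and 178 had an unadjusted p under 0.05 (71 higher, 107 lower), while voom with trend on recovered fragments, chosen after seeing the data, called 73 coding genes. Groups did not overlap for 15 of the 20, and for 9.61% of all tested genes. Chance gives 10% without ties, and with the many tied zeros here the other splits of the 6 libraries gave 6.27% to 7.21%. The median log2 difference of all tested genes was -0.49, and it was -0.74 on the TPM scale, -0.55 with median ratio scaling and -0.08 after quantile normalization. With each replicate left out it ran from -0.35 (without shNC replicate 3) to -0.78 (without shNAT10 replicate 3). The split of the calls was 7 higher and 14 lower on the TPM scale, 6 and 11 with median ratio scaling, and 7 and 16 after quantile normalization. It leaned the other way with robust eBayes (11 higher, 6 lower), a pseudocount of 0.01 (5 and 2) and without shNAT10 replicate 1 (7 and 5), and was 19 and 76 by voom with trend. Without shNC replicate 1, 2 or 3 the count was 1 each time (RNA5-8SN4), and it was 12 without shNAT10 replicate 1 and 34 without replicate 2. With shNAT10 replicates 2 and 3 both left out, an alternative chosen after seeing the data, limma called 0 genes (1139 at an unadjusted p under 0.05). The spread then came from shNC alone, and the lone library labelled shNAT10 was assumed to vary alike. Among the 22 alternatives counted for a gene, the adjusted p under 0.1 and the 1.5-fold minimum reuse the main fit. Every called gene passes both by construction. RNA5-8SN4 passed in 6 of 6 fits with a replicate left out and in 18 of 22 alternatives. These fits filtered genes over the libraries they held, the rule fixed in advance, but it was applied to them only after the counts with a filter over all 6 libraries were known: with that filter limma called 0 genes in each of the 6 fits (374 to 516 at an unadjusted p under 0.05; RNA5-8SN4 adjusted p = 0.69 to 0.743), and 52 with shNAT10 replicates 2 and 3 left out.

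**Figure D2:**
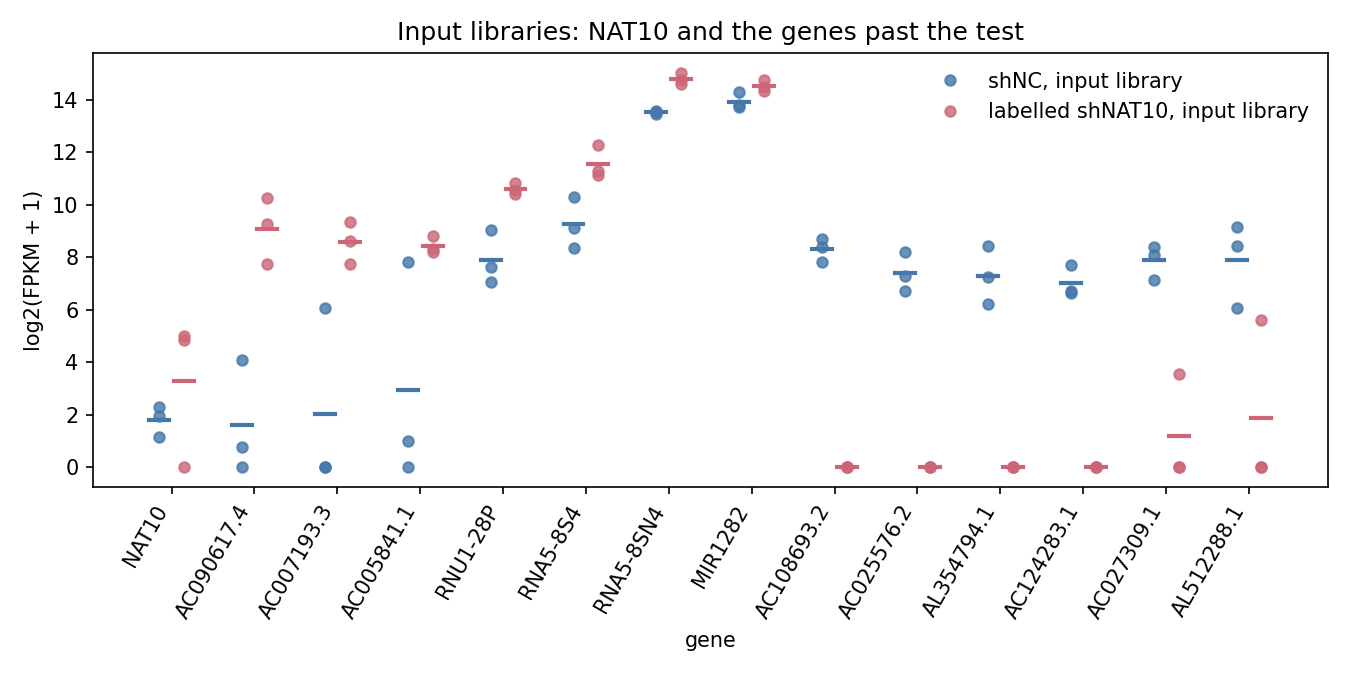
Level of NAT10 and of the named genes past the test, as log2(FPKM + 1) on the y axis, in each input library (points, 3 per group) with the group mean (bar). RNA5-8SN4 was higher in all 3 libraries labelled shNAT10, and AC108693.2 was listed at 0 in all 3.

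Among the 28 gene lists, 1 member of 1 list passed alone (RN7SL2), and 3 lists of 24 with a set test were higher in the libraries labelled shNAT10 at the preset correlation. NF-kB and inflammatory genes had a median log2 difference of 1.99 over 15 tested members (camera adjusted p = 9.29e-06 by limma, and adjusted p = 0.333 with an estimated correlation). Their median was 3.64 with a pseudocount of 0.1, 5.72 with 0.01 and 4.59 with voom. None of the 15 passed alone over all genes, and 1 did adjusted over the list alone, the chemokine CXCL2, listed at 0 in all shNC libraries and at 2.40, 167 and 166 in those labelled shNAT10. IER3, an early-response survival gene and the most abundant member, had 379, 201 and 192 against 704, 482 and 456, and did not pass (limma adjusted p = 0.754). Replication-dependent histones, which package newly made DNA, had a median of 0.26 over 40 members (camera adjusted p = 0.000294 by limma, and adjusted p = 0.183 with an estimated correlation). None of the 40 passed, over all genes or adjusted over the list alone. The median was 0.00 on the TPM scale, 0.12 with median ratio scaling, 0.05 after quantile normalization, 0.46 without shNC replicate 1 and 0.44 without shNAT10 replicate 2. Their set call was lost after quantile normalization (limma adjusted p = 0.662) and with voom (0.727). Small nucleolar RNA hosts and structural RNAs had a median of 0.54 over 14 members (camera adjusted p = 0.00069 by limma, and adjusted p = 0.319 with an estimated correlation). Of the 14, RN7SL2 passed over all genes and 3 adjusted over the list alone, and without shNC replicate 1 the set call was lost (limma adjusted p = 0.284). The median was 1.01 without shNC replicate 2, 1.14 at a mean FPKM of at least 5, 0.86 with a pseudocount of 0.01 and 0.81 after quantile normalization.

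The remaining 21 lists with a set test did not pass. Cytosolic ribosomal proteins (75 tested, median 0.18) had a camera adjusted p of 0.19 by limma, as had mitochondrial mRNAs (13 tested, median -0.31), which passed in 7 of 21 alternatives. Enterocyte and secretory genes had 1 of 12 members past the test adjusted over the list alone, KRT8, a keratin of simple epithelia, at 3112, 3774 and 3294 in shNC and 5643, 5573 and 5866 in the libraries labelled shNAT10 (log2 difference 0.75, SE 0.25, limma adjusted p = 0.598 over all genes). Every other list had 0 members past the limma test, also adjusted over the list alone, and 0 to 2 each at an unadjusted p under 0.05. Ferroptosis genes had a median of -1.06 over 23 members (1 at an unadjusted p under 0.05), Wnt targets -1.14 over 18 (0), DNA replication genes -0.96 over 32 (1), mitosis genes -0.56 over 36 (1), and tRNA and rRNA modification genes -0.11 over 18 (0). MYC, a Wnt-driven growth regulator, had 29.3, 55.7 and 60.3 against 246, 103 and 42.3. EPCAM, an epithelial adhesion molecule, had 226, 370 and 262 against 38.3, 80.3 and 128, and did not pass (limma adjusted p = 0.754). FTL, the light chain of the iron store ferritin, had 1019, 912 and 665 against 542, 1115 and 1277. AIFM2, a ferroptosis suppressor, and KIF23, a mitotic kinesin, lay below the filter. Of the markers of other cell types, 4 fibroblast and muscle genes, 1 endothelial or erythroid gene, 0 leukocyte genes and 0 neural genes were abundant enough to test, and none passed. The 4 fibroblast and muscle genes had a median log2 difference of 1.23. TAGLN, an actin-binding protein of smooth muscle, was listed at 0 in all 3 shNC libraries and at 68.9, 2.04 and 1.49 in those labelled shNAT10 (limma adjusted p = 0.754). Without a filter 11 such genes were measured, with a median of 0.65 (camera adjusted p = 0.00521 by limma).

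The authors' deposited table listed 2364 differential ac4C peaks in 1931 genes, 2255 of them in protein-coding genes. Coding sequence held 1406 peaks (59.5%), the 3' UTR 503 (21.3%), other exons 365 and the 5' UTR 88. The deposited log2 fold change was negative for 1459 peaks (61.7%, median -4.43) and positive for 905 (median 6), from -10.2 to 14.1. Between -1 and 1 lay 48 peaks. The largest differential FDR listed was 0.0501, so peaks that did not pass the authors' test were absent. The scarcity of small changes may follow from that selection. The table did not state which hairpin was the numerator. The nuclear lincRNA MALAT1 had 13 peaks, all with a positive deposited change. Several of these intervals overlapped one another, such as chr11:65502709-65502978 and chr11:65502720-65502990 (GRCh38, plus strand). AHNAK, a giant scaffold protein, had 16 (7 negative, 9 positive), and the cadherin FAT1 had 8 (3 negative, 5 positive).

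Of the 10 peaks of largest deposited fold, 6 lay in the 3' UTR. The authors listed a fold of 2860 in IPO9, a nuclear import receptor, at chr1:201877858-201878068 (3' UTR, deposited log2 change -8.21). SET, a histone chaperone, had 2650 at chr9:128693950-128694877 (3' UTR, 13). NAV1 had 2550 at chr1:201820464-201820644 (3' UTR, 10.2). RPS29, a ribosomal protein, had 2120 at chr14:49572001-49572240 (3' UTR, -8.80), NASP, a histone-binding protein, 1740 at chr1:45617506-45618155 (exon, 10.2), and MYH11, a smooth muscle myosin, 1740 at chr16:15703802-15704072 (3' UTR, 9.61). The other deposited folds were 1390 in PGPEP1, 1370 in PTP4A2, 1300 in CD55, a complement regulator, and 1270 in KITLG, the ligand of the receptor KIT. Input levels of these genes were low in places: IPO9 had FPKM 0.248, 0.230 and 0.0245 in shNC, and PGPEP1 was listed at 0 in all 3. Across the deposited table, 108 peaks (4.57%) lay in genes listed at 0 in all input libraries. No deposited peak lay in NAT10, AIFM2 or KIF23. The authors counted at least 1 site of the repeated motif CXX in 1480 peaks (62.6%), and the deposited density was 6.09 sites per 1000 nt in negative and 4.80 in positive peaks, a difference that was not tested.

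**Figure D3:**
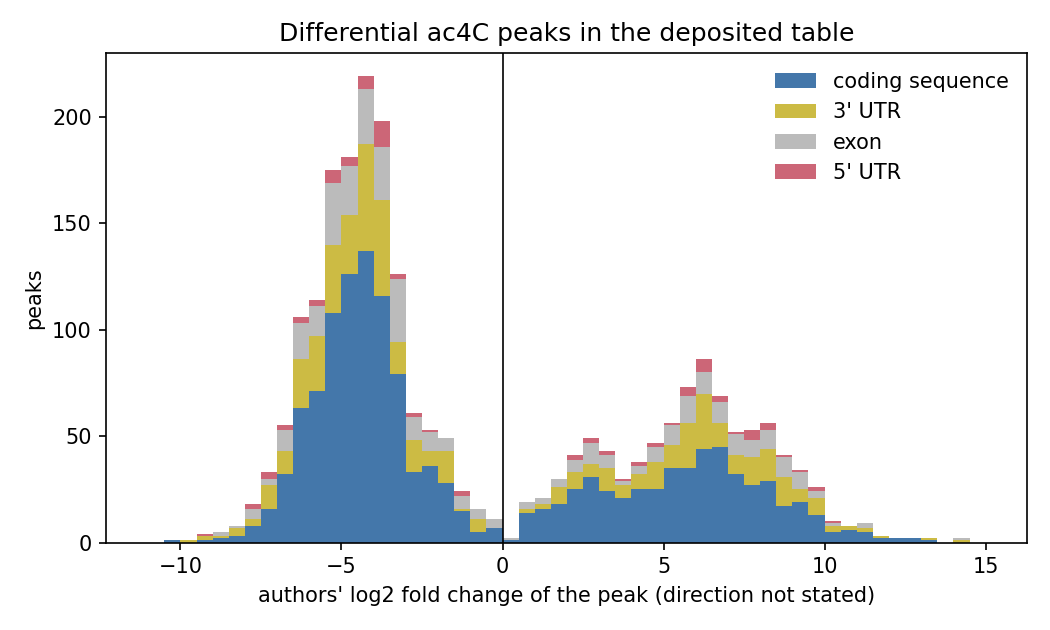
Number of deposited differential peaks (y axis) by the authors' log2 fold change (x axis, bins of 0.5, direction not stated), coloured by annotated region; 1 peak at a start codon and 1 at a stop codon are not drawn. Negative peaks (1459) outnumbered positive ones (905), and 48 lay between -1 and 1. The largest differential FDR listed was 0.0501, so small changes may be few by selection.

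No difference in input abundance was detected between genes with a deposited peak, pooled over both signs, and other genes. Their median log2 difference was -0.32 over 1616 tested genes, against -0.31 for random lists of the same level (95% of lists from -0.42 to -0.20, permutation p = 0.854, two-sided). The camera p was 0.739 by limma at the preset correlation and 0.418 with an estimated one. Pooling can hide opposite shifts. Genes with only negative peaks had a median of -0.20 (941 tested), and those with only positive peaks -0.50 (528 tested). These sets leaned up and down against other genes, and neither passed by limma's camera at either correlation. Across 2014 peaks, the deposited change and the input difference had a Spearman correlation of -0.06. Input FPKM of DNAJB1, a heat-shock co-chaperone with a peak, was 96.6, 86.5 and 158 in shNC. It was 91.3, 172 and 264 in the libraries labelled shNAT10. CENPF, a kinetochore protein with a peak, had 17.8, 23.2 and 5.39 against 8.13, 45.2 and 7.86.

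Chaperone, mitotic and DNA replication genes carried deposited peaks more often than all other expressed genes, but did not pass against random genes of like level. Of 9284 background genes 1531 (16.5%) had a peak. Heat shock genes had one in 7 of 13 (odds ratio 5.93, Fisher's exact adjusted p = 0.0303), mitosis genes in 12 of 31 (3.22, adjusted p = 0.0303) and DNA replication genes in 11 of 30 (2.95, adjusted p = 0.0491). Against random lists matched on level the permutation adjusted p were 0.0864, 0.11 and 0.128, and matched on level and length 0.149, 0.149 and 0.173. Peaks in heat shock genes included DNAJB1 (chr19:14515009-14515188, 3' UTR, deposited fold 163), HSPE1, a mitochondrial chaperonin (chr2:197501042-197501401, coding sequence, 24.5), HSP90AA1 (chr14:102085806-102085986, coding sequence, 5.61) and STIP1, a co-chaperone (chr11:64204095-64204364, 3' UTR, 4.61). Among mitosis genes the largest deposited folds were in CENPF (chr1:214619142-214622158, 375), the spindle checkpoint kinase TTK (chr6:80008487-80011902, 83.2), the proliferation marker MKI67 (chr10:128108355-128108505, 67.1) and DLGAP5 (chr14:55177124-55182414, 48.2), all in coding sequence. Among DNA replication genes they were in RRM1, a ribonucleotide reductase subunit (chr11:4135176-4138279, 3' UTR, 77.5), the origin licensing factor CDC6 (chr17:40291199-40293622, coding sequence, 46.1), TYMS, which makes thymidylate (chr18:672894-673072, coding sequence, 37.7), and GINS4 (chr8:41544089-41544268, 3' UTR, 25.1). The deposited changes in these genes had both signs, from -6.09 in RRM1 to 8.13 in HSP90AA1. Naming was not limited to background genes. TTK (input FPKM 1.94, 0 and 0 in shNC) and CDC6 (0.116, 0.059 and 0.057) lay below that filter, so the counts above leave them out. HSPE1 was above 0 in shNC replicate 1 alone (103). DLGAP5 had 14.1 there, 0.196 in shNAT10 replicate 1 and 0 elsewhere. GINS4 had 0.108 and 6.40 in shNC replicates 1 and 2 and 0 elsewhere.

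The remaining 21 lists did not pass, among them ferroptosis genes (1 of 23 with a peak) and mitochondrial mRNAs (0 of 13). Longer genes carried peaks more often, from 4.95% in the shortest of 5 length classes of background genes to 26.2% in the longest. Against random lists matched on level, 0 lists passed. Matched on level and length, an alternative chosen after seeing the data, 1 passed: histones, with a peak in 11 of 41 (26.8% against 8.93%, permutation adjusted p = 0.0144). With the stricter FDR on deposited peaks, only heat shock genes passed (adjusted p = 0.0126; mitosis 0.0544, DNA replication 0.161).

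**Figure D4:**
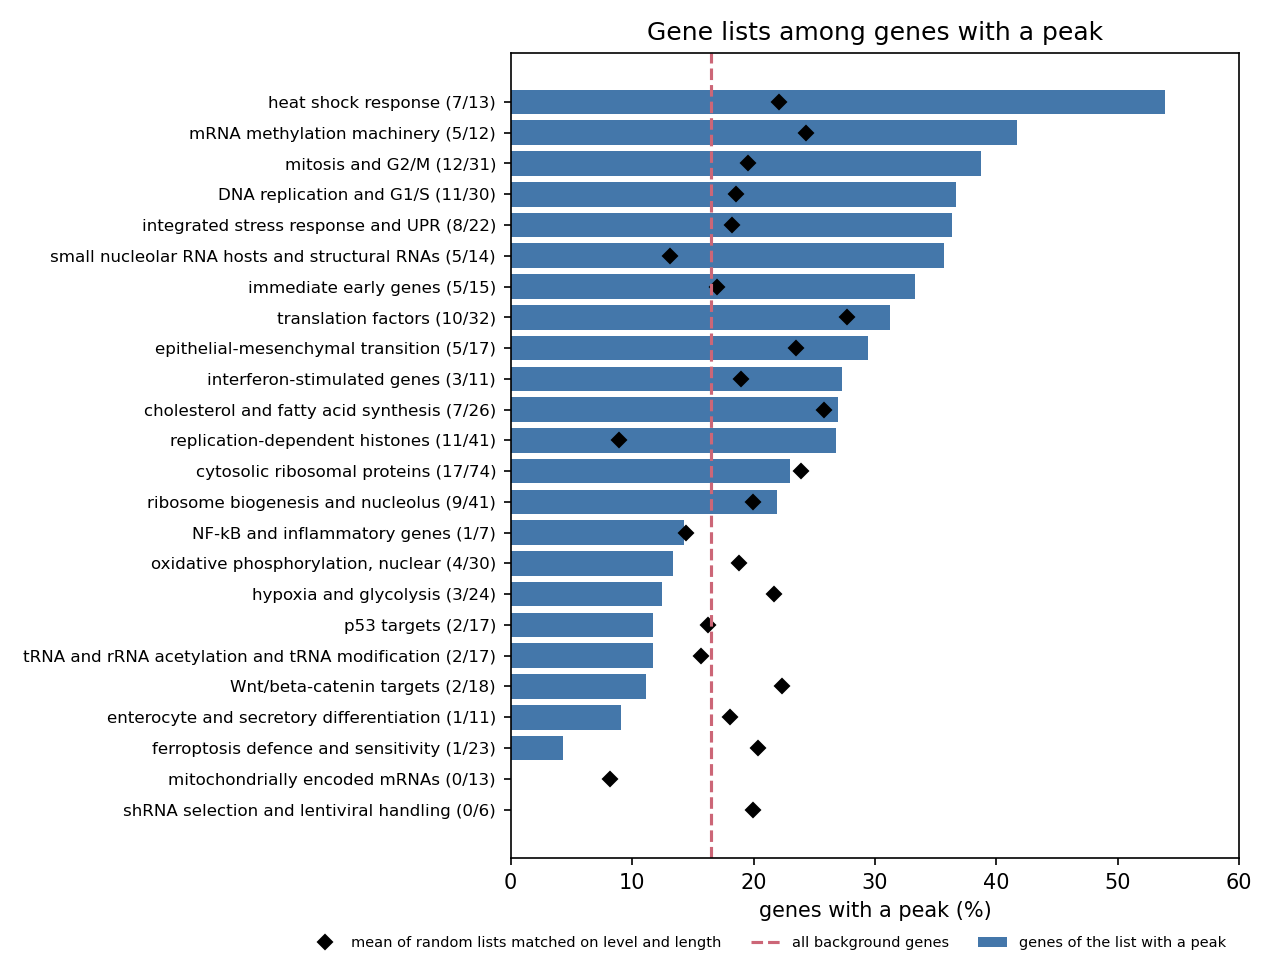
Share of each list's background genes with a deposited peak (bars, x axis in %; counts beside the names), the mean share in random lists matched on level and length (diamonds), and the share of all background genes (dashed line, 16.5%). Heat shock genes had peaks in 7 of 13 and histones in 11 of 41.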

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

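Alternatives with voom, thinning, protein-coding genes alone, 2 libraries left out, matching on length, or a filter over all 6 libraries in fits with fewer were chosen after seeing the data. The count of 20 genes was within 1.5 times with a pseudocount of 0.1 (26), TPM (21), median ratio (17), quantile (23), robust eBayes (17), a replicate block (21, of which 20 shared), an adjusted p under 0.1 (24) and a 1.5-fold minimum (20). It was 7 with a pseudocount of 0.01, 10 with a mean FPKM of at least 5, 1 with thinned fragments, and 6 for protein-coding genes alone. By limma it was 0 without a filter (340 genes at an unadjusted p under 0.05), 0 without trend (480), and 0 with shNAT10 replicates 2 and 3 left out (1139). With each replicate left out it ran from 1 to 34. With the filter over all 6 libraries it was 0 in each of these 6 fits (limma, 374 to 516 at an unadjusted p under 0.05) and 52 with shNAT10 replicates 2 and 3 left out. Voom called 95 genes with trend (9 shared) and 1 without, where the prior variance of 363 stood far above the median residual variance of 0.975. The NAT10 difference reversed to -0.23 with a pseudocount of 0.01 and to -1.81 with shNAT10 replicates 2 and 3 left out. MIR1282 reversed to -0.12 under quantile normalization. Lists in input expression numbered 0 with an estimated correlation, 0 with a replicate block and estimated correlation, and 1 with shNAT10 replicates 2 and 3 left out. Lists among peak genes numbered 9 against genes with any FPKM above 0, 1 with the stricter FDR, 0 against lists matched on level, and 1 matched on level and length. Peaks numbered 1763 past the stricter FDR and 2275 merged. The median of peak genes was -0.27 past the stricter FDR; the other alternatives for it change only its p. For the 20 called genes and the 6 lists that passed, NAT10 apart, 271 values kept their direction and side of the threshold, 236 kept only the direction, and 1 reversed. The 271 include the adjusted p under 0.1 and the 1.5-fold minimum, which no called gene could fail. Restricting peaks to exons moved nothing, since all were annotated exonic. A fit of all 12 libraries, the comparisons of immunoprecipitate with input, and the repeat search were not run. The cause of these shifts was not tested. Many ran with limma's prior degrees of freedom, 212.6 in the main fit. Fits without a filter, trend or 1 shNC replicate, or with thinned fragments, had 7.47 to 13.3 and called 0 or 1. The 6 fits filtered over all 6 libraries had 2.09 to 3.31. It was infinite for protein-coding genes alone (6 called) and voom without trend (1), so the order did not always hold. Counts with a replicate left out thus do not speak on that replicate alone. In the simulation, log2 changes of 1 and 2 were each called in 0 of 40 genes. It left out the many values at 0 and genes with a spread unlike others of their level. The real fit called a difference of 0.59 in an abundant gene (MIR1282), so the simulation sets no limit for every gene.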

Other observations

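The tests below were chosen after the results were seen, except the count of genes above 0 after thinning and the permutation of peak signs, which were chosen after the data were examined but before their own results were seen. Fitted without the noncoding genes, 6 of 8140 protein-coding genes passed (limma). In this fit the prior degrees of freedom were infinite. Each SE was thus that of genes of like level, and a gene's own spread between replicates had no weight. For this reason the SE of KRT8 differs here from the 0.25 of the fit of all genes. KRT8 rose by 0.75 (log2, SE 0.14, adjusted p = 0.000436), from FPKM 3112, 3774 and 3294 in shNC to 5643, 5573 and 5866 in the libraries labelled shNAT10, higher in 3 of 3. It did not pass on the TPM scale (0.48, limma adjusted p = 0.175), nor without shNC replicate 1 (0.477), shNC replicate 3 (0.396) or shNAT10 replicate 1 (0.058). The histone genes HIST1H2AJ, HIST1H2AI and HIST1H2BK rose by 1.34 (SE 0.27), 1.83 (SE 0.44) and 1.52 (SE 0.36). MT-CO1 and MT-ND4, mitochondrial subunits of the respiratory chain, fell by 0.76 (SE 0.16) and 0.76 (SE 0.16), although MT-CO1 in shNAT10 replicate 3 (5030) was above all shNC libraries. Without shNAT10 replicate 2 the differences were -0.17 for MT-CO1 and -0.55 for MT-ND4 (limma adjusted p = 0.816 and 0.555), and without shNAT10 replicate 3 MT-CO1 was at -1.22 (1.43e-06), so single libraries set the size of its fall. All 6 kept their direction under TPM, median ratio and quantile scaling, where 2, 4 and 5 of them passed. Without shNC replicate 1, 2 or 3 the count was 0, 1 and 0 (limma; 213, 209 and 283 at an unadjusted p under 0.05), and without shNAT10 replicates 1, 2 and 3 in turn it was 2, 7 and 5, of which 1, 2 and 5 were among the 6.

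Among all genes, 20 were called, and 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave that many; the highest other split gave 12. Among protein-coding genes alone the real split gave 6 and the highest other 2, again 1 of 10 splits. With 10 splits a share under 0.05 cannot be reached.

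AKR1B1, an aldose reductase, was listed at 0 in all 3 shNC libraries and at 63.7, 92.3 and 102 in those labelled shNAT10. It was chosen after its values were seen and did not pass (limma adjusted p = 0.133).

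NAT10 was higher in 2 of the 3 libraries labelled shNAT10 than in any shNC library. A candidate explanation is that few molecules stand behind each value: of the 500 genes of nearest mean level, 61.4% had a range over the 6 libraries as wide as that of NAT10. Libraries exchanged between the groups stay open. The lowest shNC library lay above the lowest library labelled shNAT10 by 1.16 (log2), more than the SD of 0.59 within shNC and less than the residual SD of 2.28, which holds the values in question, so this gap decides nothing. A knockdown of partial effect, or one seen in protein, was not tested.

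Fewer genes were above 0 in the libraries labelled shNAT10, by 1524 on average. Scaling of the deposited values cannot change this count, because it cannot turn a value above 0 into 0, so no test was needed. The median log2 difference of tested genes is another measure and decides nothing about the count. It was -0.55 under median ratio scaling and -0.08 after quantile normalization. Lower read depth may account for part of the gap: with all libraries thinned to the lowest total of fragments on genes, 62.96% of it was left (959 genes). At that equal total shNAT10 replicates 1 and 2 had 6306 and 6426 genes above 0, below the shNC libraries (7773 to 8075). These values argue against read depth as the whole cause in replicates 1 and 2. Replicate 3 had 8117, so the groups overlapped, and what remained was not shown to follow the hairpin. Fewer starting molecules in the shallower libraries and an effect of the hairpin stay open.

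Of 328 genes with over 1 deposited peak, 160 held peaks of both signs, where permuted signs gave a median of 172 (95% from 155 to 189, one-sided permutation p = 0.0883). This is consistent with signs that are independent from peak to peak, and a weak tendency of peaks in 1 gene to share a sign was not excluded. Overlapping peaks, as in MALAT1, are not independent, so the permuted range may be too narrow. The spread of input values between replicates was not linked to single peaks, so a biological explanation was not tested.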
